A study of Mus musculus with 10 samples.

How the data were processed

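Pancreatic islets of C57BL/6 mice were profiled by RNA sequencing in 10 libraries, 5 from mice given REGN1193, an antibody that blocks the glucagon receptor (GCGR), and 5 from mice given an isotype control antibody. Per the labels' protocols, islets were separated on a Histopaque density gradient, RNA was purified with a miRNeasy kit, and polyA RNA went into Nextera XT libraries, a kit that does not mark the strand. The antibody libraries carry the numbers 1 to 5 and the isotype libraries 6 to 10 in the labels. The labels do not say that each library came from a separate animal, nor do they give dose, duration, sex, litter or batch.

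The authors deposited 1 table of RPKM values, read numbers scaled by transcript length and library size, for 24475 genes with an Entrez identifier and a symbol. The submitters' processing notes name the builds GRCm38 and mm10, CASAVA 1.8.2 and FastQC, with no roles. The aligner, the counting program and the annotation are not given in the sources used here. Of the identifiers, 24375 were found in a RefSeq gene table of GRCm38.p6, which gave the coordinates, and 100 were not. In 417 genes, values above 0 but below 0.0001 RPKM occurred, far under the worth of 1 read, so ambiguous reads appear to have been divided among genes. Near-identical copies (the beta globin rows Hbb-bt and Hbb-b2 held the same values) are therefore uncertain as single genes.

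Depth was estimated from the steps of the low RPKM values. For 15152 genes with a single RefSeq-linked transcript length in GENCODE M21, the value multiplied by the length should rise in steps worth 1 read, and the lowest step gives the number of reads behind the library. The estimates ran from 12.4 to 18.1 megareads. Between 67.8% and 71.2% of the low values per library lay within 0.1 of a whole number of reads. A step not fitted to them would give 20% by chance. The step was chosen on the lowest of these same values, so part of that share follows from the fit. The reads themselves were not recovered for all genes, so no count model was fitted.

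RPKM values were used as log2(RPKM + 0.5) without further scaling. Genes with a mean of at least 0.5 RPKM over the 10 libraries were tested, which kept 13450. A fold change on this scale understates the change of genes near 0.5 RPKM. The antibody and isotype groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors (SE) are limma's moderated ones. Single values were also compared with a two-sided exact permutation test over all 252 assignments of the libraries, whose smallest p is 0.00794. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for depth and plots.

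Before the data were examined, 33 gene lists were fixed from general knowledge, 13 of cell types and 20 of pathways. Lists with at least 3 tested members entered limma's camera test with a preset correlation of 0.01, adjusted over 31 lists; camera with an estimated correlation and limma's fry test were run beside it. The adipocyte list had 1 tested member and was not tested. The symbol pattern for mitochondrially encoded genes matched 0 genes, so 13 of them were taken by identifier, chosen after the data were seen. For each amino acid transporter, the log2 value minus the mean log2 value of 12 alpha cell genes (Slc7a2 was left out as a transporter) was compared between groups by the exact permutation test, adjusted over 32 transporters.

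Named genes were fixed by rule beforehand: Gcg, Gcgr and Slc38a5, up to 10 called genes per direction with the largest changes among those whose groups do not overlap, every called amino acid transporter, and up to 4 members of each list with the smallest p. Other names were chosen after their values were seen and are marked as such. The limma step was tested on simulated data made from these 13450 genes, 5 against 5, with 200 changed genes in each of 10 draws. It recovered 35.5% of 1.5-fold, 78.1% of 2-fold and 95.2% of 4-fold changes, with 5.94% false calls. Each gene was drawn independently, so the simulated libraries held no correlation between genes and no outlying library. These rates therefore need not hold for the real libraries.

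Alternatives were a pseudocount of 0.1 or 1, no filter or a minimum mean of 5 RPKM, median centring, quantile normalization, trimmed mean scaling, no variance trend, robust variance, array weights, the acinar level as a covariate, the exact permutation test per gene, and leaving out each library in turn. A ductal covariate, and leaving out antibody replicate 5 and isotype replicate 10 together, were added after the data were seen, as was leaving out each library for the 13 mitochondrially encoded genes. Some single genes and 1 added reference are not reported here.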

Results

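Transcript levels were measured in islets, the hormone-secreting cell clusters of the pancreas, from 5 libraries of mice given the GCGR-blocking antibody and 5 libraries of mice given an isotype control antibody. The series concerns alpha cell hyperplasia under glucagon receptor inhibition, and the comparison asks which islet transcripts differ when the receptor is blocked. The estimated depth was 16.1 ± 1.48 megareads (M) (SD, n = 5) in the antibody libraries and 13.5 ± 1.22 M (SD, n = 5) in the isotype libraries (exact permutation p = 0.0476). At these depths 0.5 RPKM of a transcript of 2 kb rests on 12.4 to 18.1 reads. All p-values measure only the spread between these libraries, since the labels do not say that they came from separate animals.

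Gcg, which encodes proglucagon, rose 5.24-fold with the GCGR-blocking antibody. It stood at 63254 ± 11470 RPKM (SD, n = 5) against 12299.9 ± 3618 RPKM (SD, n = 5) under the isotype antibody, a log2 fold change of 2.39 (SE 0.27, limma adjusted p = 0.00174). Slc38a5, which encodes a sodium-coupled carrier of glutamine and other neutral amino acids, rose 15.01-fold, from 3.05 ± 1.25 to 52.3 ± 18.7 RPKM (SD, n = 5 each). Its log2 fold change was 3.91 (SE 0.27, limma adjusted p = 9.89e-05), the largest among the 13450 tested genes that passed the threshold. In both genes every antibody library lay above every isotype library (exact permutation p = 0.00794, the smallest that 5 against 5 allows). Gcgr, the gene of the blocked receptor, was at 11.1 ± 3.11 RPKM with the antibody and 18.1 ± 4.51 RPKM with the isotype control (SD, n = 5 each). Its log2 fold change of -0.68 (SE 0.21) did not pass over all genes (limma adjusted p = 0.375), while the single-gene exact permutation p was 0.0317. The antibody acts on the receptor protein, so Gcgr transcript is no check of the labels. In GRCm38.p6, Gcg lies on chromosome 2 from 62474530 to 62483653 (Entrez 14526), Gcgr on chromosome 11 from 120529185 to 120538989 (Entrez 14527) and Slc38a5 on chromosome X from 8271381 to 8280179 (Entrez 209837). Quantile normalization lowered the log2 fold change of Gcg to 1.41 (limma adjusted p = 0.0167). Without a filter on low values its limma adjusted p was 0.784 at the same fold change.

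**Figure D1:**
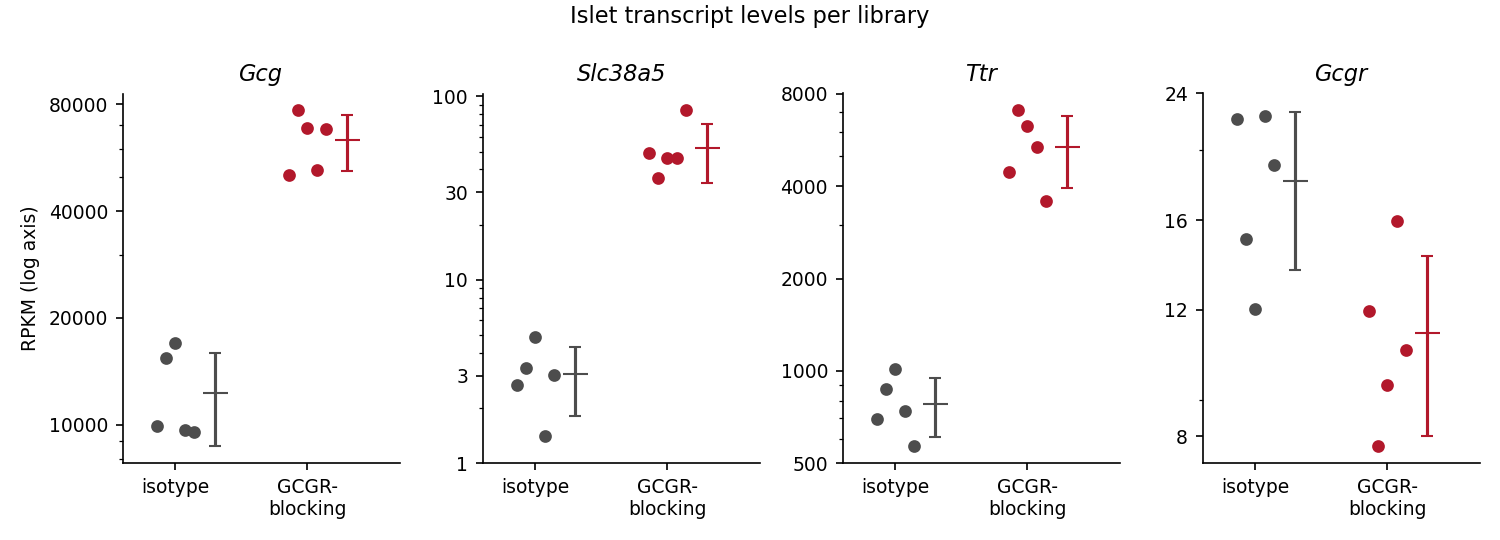
RPKM (log axis, a scale of its own in each panel) of Gcg, Slc38a5, Ttr and Gcgr in each of the 5 isotype (grey) and 5 GCGR-blocking antibody (red) libraries, with the mean and SD beside the points. The groups do not overlap for Gcg, Slc38a5 and Ttr, and they overlap for Gcgr.

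Across the transcriptome 53 genes rose and 2 fell with the antibody, out of 13450 tested with limma. After Slc38a5, the largest rises were those of Ttr, the thyroid hormone and retinol-binding protein carrier transthyretin (log2 fold change 2.77, SE 0.22), and Gcg. They were followed by Gpx3, a secreted glutathione peroxidase (2.11, SE 0.23), Sct, the hormone secretin (2.10, SE 0.26), and Guca2a, the peptide guanylin (2.10, SE 0.20). Gfra3, a subunit of the artemin receptor, rose by 1.94 (SE 0.21) on the log2 scale. The same scale gave 1.83 (SE 0.29) for the translation elongation factor Eef1a2, 1.65 (SE 0.16) for the protease inhibitor Serpine2 and 1.65 (SE 0.15) for the pyruvate dehydrogenase kinase Pdk4. Limma adjusted p for these genes ran from 9.89e-05 for Slc38a5 to 0.0158 for Eef1a2. The isotype means of Sct (0.428 RPKM) and Guca2a (0.218 RPKM) were below the pseudocount, so their folds are understated. The genes that fell were Tspan1, a tetraspanin, from 8.22 ± 5.33 to 1.40 ± 0.27 RPKM (SD, n = 5 each; log2 fold change -2.02, SE 0.32, limma adjusted p = 0.0152), and 1810011O10Rik (-0.86, SE 0.16, limma adjusted p = 0.0476). The latter lost its call in 16 of 24 alternative settings, among them the omission of any library but isotype replicate 6 (limma adjusted p up to 0.141). Tspan1 lost its call in 3 of 23, among them without antibody replicate 1 (-1.96, limma adjusted p = 0.0544). Of the 10 risen genes above, Eef1a2 lost its call in 6 of 24, among them without antibody replicate 2, antibody replicate 3 or isotype replicate 9 (limma adjusted p up to 0.0592), and Gcg in 2 of 24. The other 8 lost theirs only in the exact permutation test per gene, which no gene can pass. At an absolute log2 fold change of at least 1, 35 genes rose and 1 fell.

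In all 55 called genes the groups did not overlap, as in 267 of all tested genes, 1.99% where chance gives 0.794%. At an unadjusted p under 0.05, limma counted 382 genes higher and 562 lower, and 4512 folds lay above and 8938 below 0. This balance depended on leaving RPKM unscaled: the counts were 584 higher and 301 lower after median centring, 484 and 382 after quantile normalization, and 525 and 355 with trimmed mean scaling. No general shift of expression is therefore read from it. The number of risen genes was 32 without antibody replicate 2, 32 without antibody replicate 3 and 31 without isotype replicate 9. It was 23 with a minimum mean of 5 RPKM and 121 with array weights. With 1 library left out, the number of fallen genes ranged from 0 (without antibody replicate 1) to 20 (without isotype replicate 6), and it was 61 with array weights.

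Alpha cell genes rose as a group. Of 13 genes of alpha cell hormone and identity, 8 rose over all genes and 12 when adjusted over the list alone, with a median log2 fold change of 1.06 (camera adjusted p = 1.49e-37, adjusted p = 0.00365 with an estimated correlation; fry adjusted p = 0.000215). Besides Gcg and Ttr, the rule named Wnk3, a kinase (1.39, SE 0.18), and Smarca1, an ATPase of chromatin remodelling (0.99, SE 0.13). The transcription factor genes Irx1 (1.20, SE 0.23) and Irx2 (1.16, SE 0.17) and the vitamin D-binding protein gene Gc (1.06, SE 0.20) also passed; these were named after their values were seen. Of these, Irx2 lost its call only in the exact permutation test per gene, while Irx1 lost it in 15 of 23 alternative settings and Gc in 15 of 24. For Irx1 these included the omission of any library but isotype replicate 7 or 8, and for Gc of any but antibody replicate 4 (limma adjusted p up to 0.170 and 0.167). The member that did not pass over the list alone was the arginine transporter gene Slc7a2 (0.30, SE 0.18). The number of risen members was 4 without a filter on low values. It was 5 without antibody replicate 1, 2, 3 or 5, without isotype replicate 6 or 9, or with the acinar covariate. It was also 5 without antibody replicate 5 and isotype replicate 10 together, a setting chosen after seeing the data.

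The other islet hormones and their cell types had smaller differences, none past the threshold over all genes in the main analysis. With quantile normalization the beta cell gene Iapp, named after its value was seen, was called lower. All 5 delta cell genes had positive folds with a median log2 fold change of 0.48 (camera adjusted p = 3.51e-07; adjusted p = 0.0728 with an estimated correlation). They included Sst, somatostatin, at 6127 ± 2303 against 3294 ± 1382 RPKM (SD, n = 5 each; log2 fold change 0.92, SE 0.33), and Rbp4, retinol-binding protein (0.95, SE 0.23); 4 of the 5 were higher when adjusted over the list alone. The 3 pancreatic polypeptide cell genes had a median of 0.72 (camera adjusted p = 0.000305; adjusted p = 0.327 with an estimated correlation), with 2 higher when adjusted over the list alone. Ppy, pancreatic polypeptide, was at 4819 ± 1758 against 2840 ± 729 RPKM (SD, n = 5 each) and Pyy, peptide YY, at 3616 ± 1630 against 2071 ± 636 RPKM (SD, n = 5 each). Of 16 beta cell genes 15 had negative folds, with a median of -0.36 (camera adjusted p = 0.000597; adjusted p = 0.463 with an estimated correlation). The insulin gene activator Mafa (-0.55, SE 0.13) was the 1 member that passed when adjusted over the list alone. Glp1r, the GLP-1 receptor (-0.48, SE 0.21), Nkx6-1, a beta cell transcription factor (-0.43, SE 0.20), and the cation channel gene Trpm5 (-0.76, SE 0.29) did not pass.

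As shares of the summed RPKM, Gcg took 8.06% ± 1.38 with the antibody and 1.504% ± 0.363 with the isotype control (SD, n = 5 each; exact permutation p = 0.00794). Both insulin genes together took 33.0% ± 5.25 and 44.6% ± 4.83 (SD, n = 5 each; exact permutation p = 0.0238). The shares of Sst were 0.771% and 0.401% (exact permutation p = 0.0238), those of Ppy 0.607% and 0.346% (exact permutation p = 0.0238) and those of Pyy 0.455% and 0.253% (exact permutation p = 0.0476). These shares sum to a fixed whole, so a gain in one lowers the others.

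**Figure D2:**
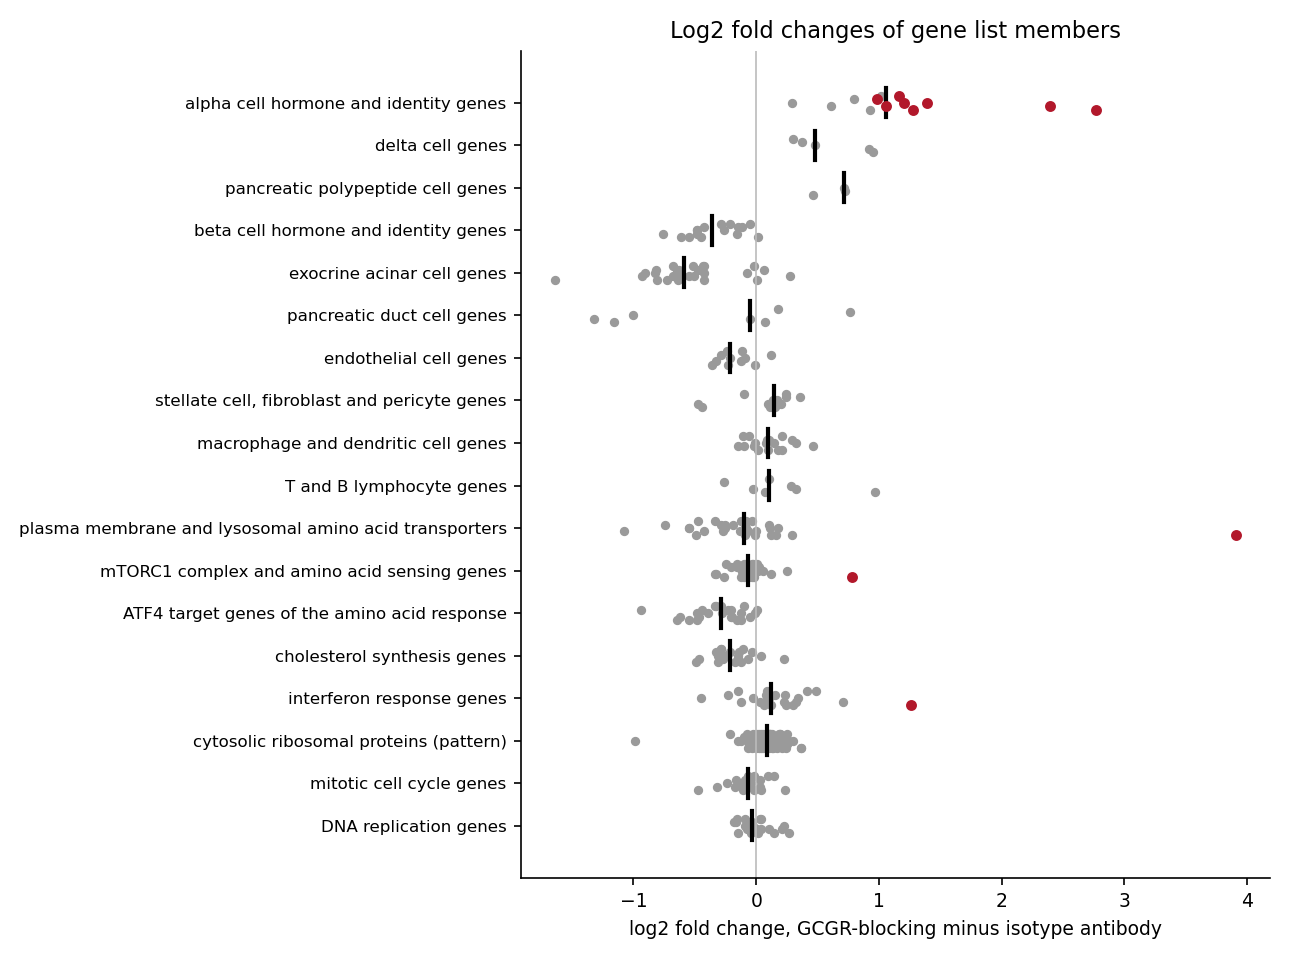
Each point is the log2 fold change (GCGR-blocking minus isotype antibody, 5 libraries each) of 1 member of a gene list, red where limma's adjusted p over all genes was under 0.05; black bars are list medians. The alpha cell median is 1.06 and the beta cell median -0.36, and Slc38a5 is the red point at 3.91 among the amino acid transporters.

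Among amino acid transporter genes, Slc38a5 rose and none of the other 31 tested passed, over all genes or when adjusted over the list alone. The median log2 fold change of the 32 genes was -0.10 (camera adjusted p = 0.454; fry adjusted p = 0.685, and 3.99e-05 for change in either direction). The last of these can rest on 1 strongly changed member, and it was not computed without Slc38a5. Slc38a3, a glutamine carrier of the same family, had a log2 fold change of -1.07 (SE 0.37), the alanine and serine carrier Slc1a4 -0.55 (SE 0.21) and the glycine carrier Slc6a9 -0.74 (SE 0.29). The mean of 12 alpha cell genes was higher by 1.30 on the log2 scale in the antibody libraries. Relative to that mean Slc38a5 was higher by a further 2.61 (exact permutation adjusted p = 0.00819), with every antibody library above every isotype library. The other 31 transporters were lower relative to that mean, which follows from its rise and says nothing of the transporters themselves. Their small p-values left the adjustment over 32 transporters almost without effect. Before it, the exact permutation p of Slc38a5 was 0.00794. With Gcg alone as the reference the difference for Slc38a5 was 1.52, and with the median of the alpha cell genes without Gcg it was 2.86.

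**Figure D3:**
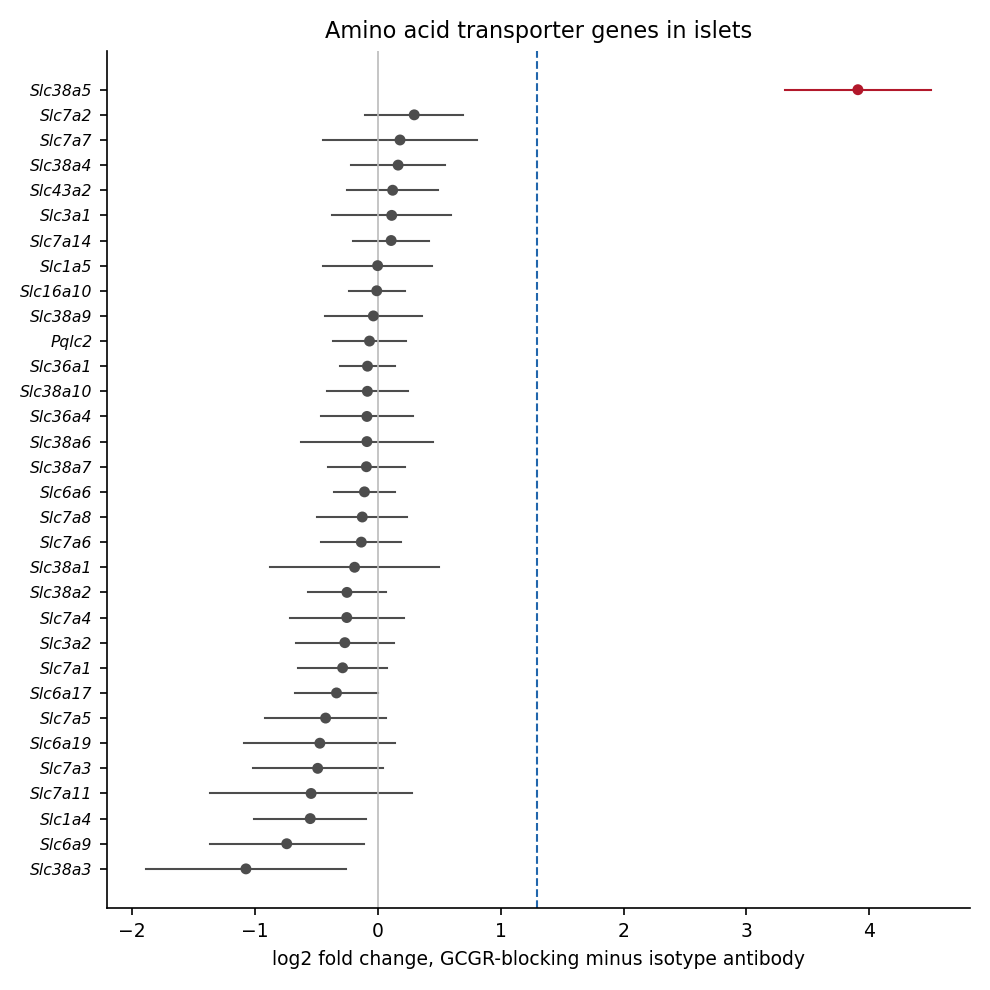
Log2 fold change (GCGR-blocking minus isotype antibody, 5 libraries each) of the 32 tested amino acid transporter genes, with limma's 95% intervals, red where the adjusted p over all genes was under 0.05. The dashed line marks the mean change of 12 alpha cell genes, 1.30; Slc38a5 at 3.91 is the single gene above it.

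Of 35 genes of the mTORC1 complex and amino acid sensing, 1 rose, over all genes and when adjusted over the list alone. It was Rragb, a Rag GTPase that links amino acids to mTORC1 (19.0 ± 1.24 to 33.2 ± 3.17 RPKM, SD, n = 5 each; log2 fold change 0.78, SE 0.10, limma adjusted p = 0.00346). Its relative Rragd had a log2 fold change of -0.34 (SE 0.14), and the list median was -0.06 (camera adjusted p = 0.876). Of 24 ATF4 targets of the amino acid response 23 had negative folds, among them the glutathione-degrading enzyme gene Chac1 (-0.65, SE 0.24) and the stress gene Ddit4 (-0.28, SE 0.12). The median was -0.28 (camera adjusted p = 0.000725; adjusted p = 0.726 with an estimated correlation), and no member passed over all genes or when adjusted over the list alone. The call was lost without antibody replicate 5 (median -0.19, camera adjusted p = 0.0707), without it and isotype replicate 10 together (-0.14, 0.0807), and with the ductal covariate (-0.23, 0.102), the last 2 chosen after seeing the data. The aminoacyl-tRNA synthetases had a median of -0.16 (camera adjusted p = 0.150) and the amino acid breakdown genes -0.06 (camera adjusted p = 0.494). In other settings the synthetase list gained a call in 3 of 25 and the breakdown list in 2 of 25. In the latter list the camera test pointed upward against the sign of the median, and Arg1, arginase, was at 59.6 ± 21.5 against 32.0 ± 10.2 RPKM (SD, n = 5 each; log2 fold change 0.85, SE 0.27, limma adjusted p = 0.418).

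Cell cycle genes did not pass over all genes, nor did their lists in the main analysis. The 21 tested mitotic genes had a median log2 fold change of -0.07 (camera adjusted p = 0.876, direction upward), with the cyclin gene Ccnb2 at -0.47 (SE 0.25) and the kinase gene Cdk1 at -0.32 (SE 0.23). Cdk1 stood at 0.844 ± 0.338 and 1.19 ± 0.454 RPKM (SD, n = 5 each), near the filter on low values. The mean log2 level of the mitotic list ran from 0.08 to 1.04 in antibody libraries and from 0.08 to 1.25 in isotype libraries. The estimated correlation between its genes was 0.81. With that spread, the missing call is no evidence that cell division was unchanged. With the ductal level as a covariate, chosen after seeing the data, the mitotic median was 0.26 (camera adjusted p = 0.00332). The 22 DNA replication genes had a median of -0.03 (camera adjusted p = 0.327, direction upward). They passed without antibody replicate 4 (median 0.05, camera adjusted p = 0.0321), without isotype replicate 10 (0.07, 0.0255) and with the ductal covariate (0.12, 0.00151). The 11 cell cycle inhibitors and D cyclins had a median of -0.12 (camera adjusted p = 0.894). Endocrine progenitor genes had a median of 0.05 (camera adjusted p = 0.289), with the transcription factor gene Fev at 0.83 (SE 0.24).

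Further lists gave small differences. The interferon response list had 1 risen gene of 23, Ifih1, a sensor of double-stranded RNA (log2 fold change 1.26, SE 0.13, limma adjusted p = 0.00129), which was also the 1 that passed when adjusted over the list alone. The list median was 0.12 (camera adjusted p = 1.51e-05, and 0.343 with an estimated correlation), and Mx1, a classical interferon-induced gene, was at -0.45 (SE 0.16). Mx1 stood at 0.377 ± 0.132 RPKM with the antibody and 0.689 ± 0.0754 RPKM with the isotype control (SD, n = 5 each), near the filter on low values. The medians were 0.09 for 76 ribosomal protein genes (camera adjusted p = 9.25e-08; adjusted p = 0.726 with an estimated correlation) and 0.08 for 22 secretory granule genes (0.00431; adjusted p = 0.555 with an estimated correlation). In the granule list Chgb, chromogranin B, was at 0.69 (SE 0.26) and Chga, chromogranin A, at 0.04 (SE 0.22), the latter named after its value was seen. The granule list did not pass without isotype replicate 10 (median 0.04, camera adjusted p = 0.111), without a filter on low values (0.0578), with quantile normalization (0.123), or with the acinar (0.0588) or ductal covariate (0.0697). For 19 cholesterol synthesis genes the median was -0.21 (camera adjusted p = 0.00347; adjusted p = 0.555 with an estimated correlation). The cholesterol list did not pass without isotype replicate 8 (median -0.19, camera adjusted p = 0.0750) or with the acinar (0.0971) or ductal covariate (0.107). Glucagon family receptors and cAMP pathway genes (median -0.10, camera adjusted p = 0.408), endoplasmic reticulum chaperones (-0.12, 0.756), glycolysis genes (-0.20, 0.339), nuclear-encoded respiratory chain genes (-0.04, 0.623) and islet adhesion genes (0.11, 0.483) did not pass in the main analysis. For the respiratory chain genes the test pointed upward against the sign of the median. The respiratory chain list gained a call in 3 of 25 alternative settings and the glycolysis list in 2 of 25. Immediate early and heat shock genes had a median of -0.35 (camera adjusted p = 0.105), a result that depended on the processing. They passed in 8 of 25 alternative settings: with each of the 3 scalings, with the acinar covariate, and without antibody replicate 2 (median -0.51, camera adjusted p = 0.000633), antibody replicate 3 (-0.45), isotype replicate 6 (-0.62) or isotype replicate 10 (-0.35). With 1 library left out the median was weakest without isotype replicate 9 or antibody replicate 4 (-0.19 in each), and with the ductal covariate it was -0.09 (camera adjusted p = 0.946). Adjusted over the list alone, 1 gene passed among the immediate early and heat shock genes, the heat shock gene Hspb1 (-0.85, SE 0.20), and 1 among the adhesion genes, the E-cadherin gene Cdh1 (-0.37, SE 0.11).

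In the lists of other cell types, no gene passed over all genes. The 26 acinar genes had a median log2 fold change of -0.59 (camera adjusted p = 0.00431; adjusted p = 0.895 with an estimated correlation), and 1, the acinar transcription factor gene Ptf1a (-1.64, SE 0.35), passed when adjusted over the list alone. The acinar call was lost with the ductal covariate and without antibody replicate 1, 2 or 3 (medians -0.48, -0.43 and -0.42) or isotype replicate 6 or 8 (-0.44 and -0.41). Without isotype replicate 9 the median was -0.99, and without antibody replicate 5 it was -0.90. In single libraries acinar genes took from 0.541% (isotype replicate 9) to 2.65% (isotype replicate 8) of the summed RPKM. The duct list had a median of -0.05 (camera adjusted p = 0.404), with 2 of 7 lower when adjusted over the list alone: Krt19, keratin 19 (-1.32, SE 0.40), and Tff2, a mucosal trefoil peptide (-1.16, SE 0.35). Red blood cell genes had a median of 0.53 (camera adjusted p = 0.0146, and 0.555 with an estimated correlation). The rows Hbb-bt and Hbb-b2, equal in every library, both entered this list of 5 tested genes and set its median. The red blood cell call was lost in 10 of 24 alternative settings, among them all 3 scalings and the ductal covariate (median -0.0029). It was also lost without antibody replicate 1 (median 0.12) or isotype replicate 7 (0.39), 9 (0.37) or 10 (0.49), while without antibody replicate 2 the median was 0.86. Endothelial (-0.21, camera adjusted p = 0.404), mesenchymal (0.14, 0.404), macrophage and dendritic (0.10, 0.105), lymphocyte (0.10, 0.105) and Schwann cell lists (-0.17, 0.925) did not pass. Some gained a call in other settings, the macrophage and dendritic list in 5 of 25 and the lymphocyte list in 4 of 24. With 1 library left out, medians ranged from -0.17 to 0.57 for mesenchymal genes and from -0.10 to 0.35 for macrophage and dendritic genes. For lymphocyte genes they ranged from -0.31 to 0.40. The 13 mitochondrially encoded genes had a median of 0.44 (limma camera p = 4.01e-09 with the preset and 0.108 with an estimated correlation). They took 19.8% of the summed RPKM in antibody replicate 5 against 5.57% to 9.50% in the other 9 libraries. Without that library, a fit chosen after seeing the data, their median was 0.21. With the preset correlation 11 of 31 lists passed, with an estimated correlation 1, and by fry 1, the alpha cell list in both. Of 100 splits of the libraries into 5 and 5, the real one included, 53 gave 11 or more lists with the preset correlation.

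Antibody replicate 5 stood apart from the rest. On the component that held 24.9% of the variance it scored 57.1, and the others lay between -22.2 and 5.56. Isotype replicate 10 stood apart on the component with 20.02% of the variance, at 45.7 against -23.3 to 14.6. Without both libraries, a choice made after seeing the data, 37 genes rose and 5 fell, and 35 of the 55 called genes remained. The log2 fold changes were then 2.28 for Gcg (limma adjusted p = 0.00652) and -0.65 for Gcgr (limma adjusted p = 0.608).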

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

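The tests on antibody replicate 5 and the ductal covariate for Tspan1 were chosen only after the results were seen. The acinar covariate was planned for all genes, and its use to weigh Tspan1 was chosen after. The counts over splits of the libraries were planned before, except that with an estimated correlation, which was added once the count with the preset one was seen. Of 322 groups of 5 libraries, for named genes and list means, 16 (4.97%) held 1 library far from the other 4, and chance gives about 5%. Of these 16, 10 were in antibody replicate 5.

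In antibody replicate 5, lymphocyte genes were the highest of their group: Cd2 at 6.84 RPKM (next highest 1.45), Cd3g at 3.50 RPKM (0.636) and Cd79a at 31.6 RPKM (5.87). The same library was lowest for Rbp4 at 119 RPKM (next lowest 210.02), Sox10 at 0.589 RPKM (0.980), the alanine and serine carrier Slc1a4 at 2.64 RPKM (4.58) and the alanine transaminase gene Gpt2 at 1.35 RPKM (3.35). Its mean log2 level was also lowest for amino acid breakdown genes at 2.86 (3.40), ribosomal protein genes at 8.03 (8.47) and nuclear-encoded respiratory chain genes at 5.36 (5.95). In antibody replicate 1, the Schwann cell gene Cdh19 was highest at 0.832 RPKM (0.577). In isotype replicate 9, Ifih1 was lowest at 3.09 RPKM (4.21), Hspa1b highest at 8.66 RPKM (3.19) and the mean log2 level of acinar genes lowest at 5.65 (7.45). Isotype replicate 10 was lowest for Mx1 at 0.560 RPKM (0.694), and isotype replicate 7 for the mean log2 level of ribosomal protein genes at 8.15 (8.41).

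Lymphocytes in the preparation may account for part of the distance of antibody replicate 5: all 7 tested lymphocyte genes were highest there of all 10 libraries, where 16.5% of all tested genes were. Cd2, Cd3g and Cd79a, already flagged above, are among the 7, so that count partly restates them. The filter on low values used the mean of all 10 libraries, and 7 of the 10 lymphocyte genes found passed it. High values in antibody replicate 5 helped Cd3d and Cd3g to pass, whose medians in the other libraries were 0.297 and 0.330 RPKM. The count is thus partly set by the filter. Ms4a1 (5.14 RPKM) marks B cells, and Cd3d (1.82 RPKM) marks T cells. More mitochondria in its cells might raise nuclear-encoded respiratory chain genes too, but 59 of 82 were lowest there (51 after median centring, where 22.4% of all genes were). This count restates their low mean given above, and 50 of 76 ribosomal protein genes were lowest there too. The low level was thus not particular to respiratory chain genes, and the count cannot decide about mitochondria. What raised its 13 mitochondrially encoded transcripts stays open. The design names no biological difference within a group, so none from it was tested.

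Tspan1 was lower in every antibody library. Less duct tissue in the antibody preparations could lower it. With the ductal level as a covariate the upper 95% bound of its log2 fold change was -1.05, and with the acinar level -1.18. Neither list mean thus accounts for the whole difference. Yet 3 of the 7 tested duct genes had positive folds, and Krt19 kept -0.71 (SE 0.26) with the ductal covariate. The duct list is therefore a weak measure of duct tissue, and its fit cannot decide about that tissue. Tissue that these lists do not track stays open, as does the antibody itself, and Reg3b, an epithelial stress gene chosen after its value was seen, was at -2.46 (SE 0.61, limma adjusted p = 0.187) with the ductal covariate.

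Of 100 splits of the 10 libraries into 5 and 5, the real one included, only the real one gave 55 called genes. The highest of the others gave 12, so a random split of these libraries was an unlikely source of that count. The splits treat the libraries as independent, which the labels do not establish. A batch or shared animals that followed the groups could give the same outcome, so these are not excluded. For the 11 lists called with a preset correlation chance cannot be excluded, since 53 of the 100 splits gave as many and the highest other gave 17. With an estimated correlation, 3 of the 100 splits gave 1 list or more, the real one (1 list) included. As the highest other also gave 1, chance was unlikely for that count but cannot be excluded.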

How the results depend on the processing

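The ductal covariate and the fit without antibody replicate 5 and isotype replicate 10 were chosen after seeing the data; the others were planned. No paired analysis was possible because the groups share no replicate numbers. Slc38a5 had log2 fold changes of 3.68 to 4.18 and Gcg of 1.41 to 2.61 over all settings, and Gcgr of -0.94 to -0.57 without passing in any. The log2 ratio of Slc38a5 to alpha cell genes differed between the groups by 1.52 to 2.86 over the settings tried. It passed in each, but the adjustment over the transporters had little effect. The rise of the reference gave nearly all of them small p-values. The alpha cell list passed in every setting, with medians of 0.99 to 1.26.

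Without a filter on low values, 1 gene fell (Sucnr1) and 40 rose, 4 alpha cell genes rose, the mitotic median was -0.060, and Gcg at 2.39 had a limma adjusted p of 0.784. The variance trend then gave Gcg a prior variance of 19.4, against 0.311 with the filter and 0.119 in its own values. A minimum of 5 RPKM left 8384 genes, of which 23 rose and 0 fell (146 and 322 at an unadjusted p under 0.05), with a transporter median of -0.10. Median centring gave a mitotic median of 0.012, quantile normalization -0.051 with 5 fallen genes, and trimmed mean scaling -0.0050; positive folds made up 33.5% of genes without scaling and 53.2%, 47.6% and 48.5% with these. Without a variance trend 1 gene fell. Array weights gave 121 and 61 genes. With the acinar covariate 5 genes fell and 5 alpha cell genes rose. The exact permutation test per gene passed 0 higher and 0 lower, since its smallest adjusted p is 0.400 (378 and 583 at an unadjusted p under 0.05), Gcg at 2.39 and Slc38a5 at 3.91 included. The ductal covariate gave 4 fallen genes, a mitotic median of 0.26 and a transporter median of -0.071. Without antibody replicate 5 and isotype replicate 10, 5 genes fell, 5 alpha cell genes rose, the mitotic median was -0.012, and the chaperone list turned to 0.10 (camera adjusted p = 0.0365). Except where a value above shows it, the cause was not tested.

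With an estimated correlation 1 list passed and by fry 1. Beta (-0.36), delta (0.48) and pancreatic polypeptide (0.72) lists lost their calls in both (fry adjusted p = 0.184, 0.0558 and 0.184), and the mitotic list (-0.065) turned downward by fry. Leaving out 1 library gave 31 to 50 risen and 0 to 20 fallen genes, 5 to 7 risen alpha cell genes and mitotic medians of -0.21 to 0.10. Depth limits low genes: 0.5 RPKM of a 2 kb transcript is 12.4 to 18.1 reads.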

Other observations

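The tests of 2 explanations in this part were chosen only after the results were seen, although the ratios and the acinar covariate behind them were planned as analyses. The genes named, except for Slc38a5 and Gcg, were chosen after their values were seen. Of the 53 risen genes, 42 were in none of the fixed lists. They included Sstr2, a somatostatin receptor (log2 fold change 1.30, SE 0.14), Avpr1b, a vasopressin receptor (1.48, SE 0.20), Kcnk3, a potassium channel (1.29, SE 0.17), and Cidea, a lipid droplet protein (1.22, SE 0.18), all by limma. Each kept its call in all settings but the exact permutation test per gene, which no gene can pass, and others of the 42 did not. These are single genes, and no shared function was tested among them. The rises of Sstr2, Avpr1b, Kcnk3 and Cidea lay near 1.30, the rise of the mean alpha cell level used as the reference for the transporters. That closeness depends on the pseudocount. The isotype means of Sstr2 (0.877 RPKM), Cidea (0.638 RPKM) and Avpr1b (1.24 RPKM) were near it, so their folds are understated. Over the alternative settings these reached 1.63, 1.63 and 1.735, so no conclusion is drawn from the closeness. A larger number of alpha cells could raise such genes without a change per cell. Whole islets do not separate these possibilities, so both stay open, also for the risen genes of the fixed lists.

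A larger number of alpha cells alone might raise Slc38a5 together with the alpha cell genes. It would leave the ratio between them level if alpha cells alone held these transcripts, at an unchanged level per cell. The log2 ratio was higher in antibody libraries by 1.52 against Gcg and by 2.61 against the mean of 12 alpha cell genes. Against their median without Gcg it was higher by 2.86. Each had an exact permutation p of 0.00794, the smallest that 5 against 5 allows. Slc38a5 thus rose more than these references. The alpha cell genes did not keep level ratios to each other either, with Gc at 1.06 and Gcg at 2.39. The ratios therefore cannot decide whether alpha cell number is the whole cause. Carryover of acinar tissue could bring Slc38a5 transcripts, but only with the abundant acinar ones. These were not higher in the antibody libraries, with a median log2 fold change of -0.59 (-0.99 to -0.41 with 1 library left out), which argues against it. With the acinar level as a covariate the lower 95% bound for Slc38a5 was 3.82, but for the same reason that fit could hardly have removed the rise. In that fit the SE of Slc38a5 was 0.17, against 0.27 without the covariate. Within the groups, part of its spread thus followed the acinar level. Whether alpha cells alone held the transcript was not tested. An effect of the antibody on Slc38a5 transcript in single cell types was not tested here, since whole islets do not separate them, and it stays open.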
